A study of Mus musculus with 2 samples.

How the data were processed

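The series compared RNA of mouse mucosal mast cell cultures at day 4 and day 20 on 2 two-colour Agilent arrays. Per the labels, total RNA was isolated with a Qiagen kit, its quality was checked on a Bioanalyzer, and it was made into labelled cRNA by linear amplification. Each labelled sample was a pool of 3 samples, and array 2 used pools of different origin with the dyes swapped, so the arrays are 2 biological replicates.

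The authors scanned each array and measured the spots with Agilent Feature Extraction, version 7.5 per the labels and 7.5.1 per the file header of array 2. The deposited scanner files hold, for each spot and dye, the mean signal and the local background as raw intensity values with no normalization. They also hold processed signals, intensity values from which the authors' software had subtracted a background and which it had then normalized between dyes along the intensity range. The background it subtracted differed between the arrays. On array 1 it was each spot's local background mean plus a constant per dye, 44.1 for Cy3 and 6.11 for Cy5, and on array 2 it was a fitted surface across the slide. The deposited log10 ratios were made by the same software from the processed signals as Cy5 over Cy3. The deposited series matrix equals these log10 ratios in 22393 of 22393 rows of each array at a tolerance of 1e-06, with medians of 0.000760 and 0, and its signs were not turned for the dye swap. In the file of array 1 a spreadsheet had turned some background medians into month names. These were read back as numbers for 313 Cy3 and 324 Cy5 cells.

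Log2 ratios were computed anew with R 4.3.3, limma 3.58.1 and the data.table package (1.17.8). The median local background was removed from the mean signal by normexp with an offset of 50, and each array was normalized by loess, with control spots and outlier-marked spots given no weight. Spots that the software marked as non-uniform or population outliers were left out, and spots of the same probe were averaged. The ratio of array 2 was turned so that every value is day 20 over day 4. Of 20868 probes for genes, 20571 had an unmarked value on both arrays. Probes were named by their RefSeq accession with the symbols of mouse assembly GRCm38.p6 (8947 probes), by the symbol in their description (371), by an older symbol there (362) or by a symbol that the RefSeq table lacks (138), and 11050 kept an accession alone. Of 8418 accession-named probes with a symbol in their description, 3556 carried another symbol, many of them older. The probes of F13a1, Rprm, Nmb and Rpl14 carry clone names in the files, and the probe of Egfl7 is described there as Vezf1. The probe of Ms4a2, named by its accession, is described there as Ms4a1, which the RefSeq table lists as a synonym of Ms4a2 and which is also the symbol of another tested gene. For each of 20415 gene names the probe with the highest mean signal was used. Genes were tested if the software called them well above background in both day 4 channels or in both day 20 channels, which left 18061, of which 8471 had a plain symbol. Signal over background differed between channels: the median net signal of gene spots was 2.79 times that of 162 negative control spots for day 4 and 7.27 times for day 20 on array 1, and 4.28 and 1.65 times on array 2.

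The comparison used limma's lmFit and eBayes against 0, two-sided, with Benjamini-Hochberg adjusted p below 0.05. The p-values rest on 2 arrays with 1 residual degree of freedom per gene, so limma's prior (12.1 degrees of freedom, SD 0.163) carries most of the variance estimate. No dye term was fitted, since it would leave 0 residual degrees of freedom. The mean of the swapped arrays cancels a gene-specific dye effect, while the spread between them contains it. A total of 26 gene lists were fixed in advance for mast cell products and receptors, mediator and cytokine genes, TGF-β and STAT5 signalling, transcription factors, other blood and stromal cells, progenitors, cell division, interferon response, glycolysis, cholesterol, lysosome, heparan sulphate, ribosomal and reference genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and counts are also given adjusted over the list alone. Lists share members, for example 2 of 12 in the protease list and 6 of 27 in the transcription factor list. Camera with an estimated correlation and fry were run beside it. On 2 arrays the former estimates the correlation from 1 residual degree of freedom per gene and tests with the same number. It can therefore hardly pass, and its high p-values do not decide whether a list moved. Camera with the preset correlation compares members with the other genes. Its small p-values measure spread across genes and not between the 2 arrays. They do not show whether a shift would repeat in other cultures. The rule for named genes took the 15 largest rises and the 15 largest falls among genes past the threshold in the same direction on both arrays and with a plain symbol, up to 4 members past the threshold with the largest change from each list, and always Mcpt1, Mcpt2, Cpa3, Kit, Fcer1a, Ms4a2, Il1rl1, Hdc, Mitf, Gata1, Gata2, Itgae, Htra1 and Havcr2. Further members that the text names illustrate a list, and the values of 2 genes that the rule named are not reported here. These lists, tests, rules and the alternatives listed next as planned were chosen before the data were examined.

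The pipeline was tested on simulated data in 20 draws of 200 changed genes each. With limma's prior a median of 98.0% of changes of log2 1 and 16.5% of changes of log2 0.5 were recovered, and a median of 11.3% of the calls were false, up to 37.5%. With a prior fitted by maximum likelihood the medians were 94.5%, 5% and 5.38%. The draws were simulated with 6.12 prior degrees of freedom, the maximum-likelihood estimate from these data, so that prior suits them by construction. Each draw also changed far fewer genes than were called in the data, so these false shares do not carry over to the reported counts. With lists of the tested sizes placed at random genes, a simulated shift of -0.3 in a list of 28 genes was found, and 0 other lists were called. Members of a real list may move together, which this simulation did not test. The alternatives planned were no background correction, a normexp offset of 0, the scanner software's log ratio and the series matrix, median centring in place of loess, scaling between arrays, no filter on dim probes, a filter on all 4 channels, the mean of a gene's probes, marked spots kept, an intensity trend with a robust prior, leaving out each array, and the other list tests. Background means in place of medians and a prior by maximum likelihood were added after seeing the data. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.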

Results

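RNA from mouse mucosal mast cell cultures was compared between day 4 and day 20 of differentiation in medium with IL-3, IL-9, stem cell factor and TGF-β1. Mucosal mast cells are the mast cells of epithelial surfaces such as the gut lining, and this cytokine mixture gives cells of that type in culture. The labels do not name the cells that were put into culture. Each of 2 two-colour arrays held both days side by side, so each array gave its own ratio of day 20 over day 4. On array 1, day 4 was labelled with Cy3 and day 20 with Cy5, and on array 2 the dyes were swapped. Each labelled sample was a pool of 3 samples, and the arrays used pools of different origin, so n = 2 biological replicates for every value. The arrays' number limits the precision.

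Of 21318 spots for genes, 96.2% were well above background in the day 4 channel of array 1 and 93.1% in its day 20 channel. On array 2 the shares were 90.5% for day 20 and 80.0% for day 4. After probes were reduced to 1 per gene name and dim probes were left out, 18061 genes were tested. The log2 ratios of both arrays, each written as day 20 over day 4, had a Pearson r of 0.77 and a Spearman rho of 0.47. This correlation is across genes, which are not independent replicates. Read as scanned, Cy5 over Cy3, the Pearson r was -0.77, so the arrays ran in opposite dye orientations, and this cannot show which day each dye held. The pooled SD of a log2 ratio between the replicates was 0.19. A total of 192 genes were at least 2-fold higher and 148 at least 2-fold lower at day 20 on both arrays, while 0 genes were at least 2-fold apart in opposite directions. Array 1 taken alone held 244 genes at least 2-fold higher and 373 at least 2-fold lower, and array 2 alone held 339 and 195. The counts on both arrays were 309 higher and 331 lower with a normexp offset of 0, and 317 higher and 364 lower with the scanner software's log ratios, so which direction held more genes depended on the setting.

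**Figure D1:**
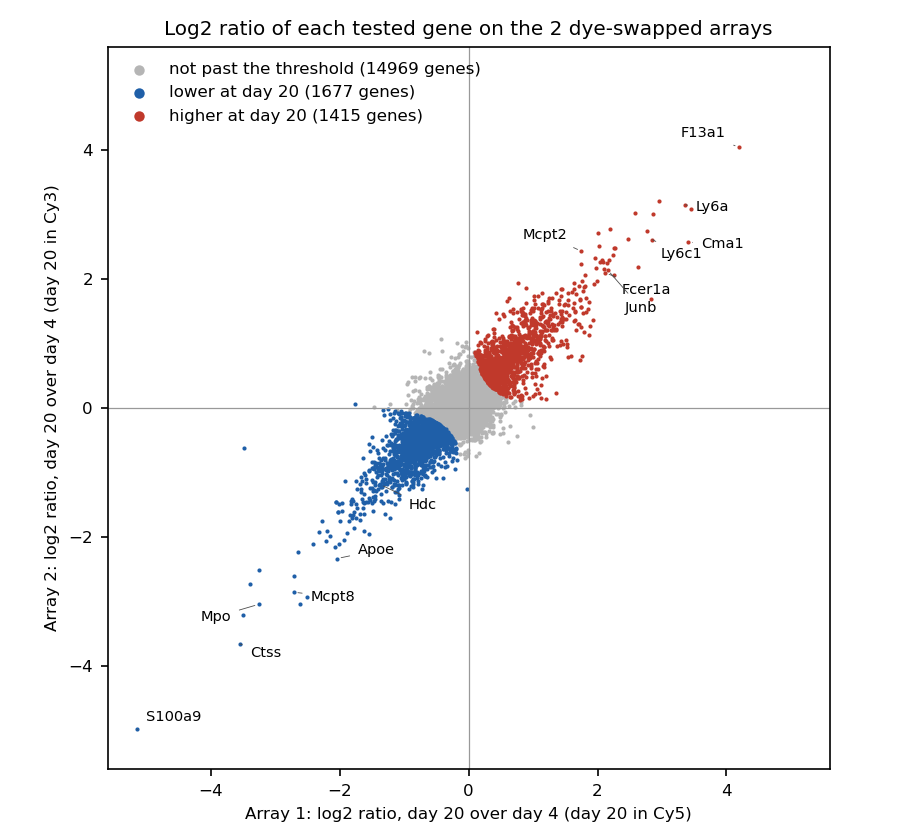
Log2 ratio of day 20 over day 4 for each of 18061 tested genes on array 1 (horizontal axis) and array 2 (vertical axis), with 1415 genes that passed the test as higher in red, 1677 as lower in blue and the others in grey. Both arrays place F13a1 at the upper right (mean 4.12) and S100a9 at the lower left (mean -5.06).

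The labels state the search for genes specific to mucosal mast cells as the purpose, and the comparison of day 20 with day 4 shows which genes rose or fell over the culture. Mast cell granule and receptor genes were among those that rose: mean log2 ratios were 2.09 ± 0.48 for Mcpt2, a chymase of mucosal mast cells, and 2.11 ± 0.01 for Fcer1a, the IgE-binding chain of the high-affinity IgE receptor (SD, n = 2). Neutrophil genes were among those that fell: S100a9, which encodes a calcium-binding protein abundant in neutrophils, had a log2 ratio of -5.06 ± 0.11, and Mpo, the myeloperoxidase of neutrophil granules, -3.15 ± 0.15. Camera also placed the lists of red cell genes (9 of 18 fell), DNA replication genes (19 of 28) and mitosis genes (8 of 22) as lower. Each had an adjusted p = 0.727 by camera with an estimated correlation, a test that can hardly pass on 2 arrays. The mitosis list had a median of -0.45 on array 1 and -0.10 on array 2. In all, 1415 genes were higher and 1677 lower at day 20 with limma at an adjusted p below 0.05, which is 17.1% of the genes tested.

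Several of the 15 largest rises were outside the mast cell lists. F13a1, the A chain of coagulation factor XIII, had the largest rise by the rule for named genes, a log2 ratio of 4.12 ± 0.11 or 17.4-fold. Ly6a, which encodes the stem cell antigen Sca-1, rose by 3.26 ± 0.15, and its relative Ly6c1 by 2.73 ± 0.17. Hs3st1, a heparan sulphate 3-O-sulphotransferase, rose by 2.38 ± 0.15. Cadm1, an adhesion molecule found on mast cells, rose by 2.36 ± 0.51, and the immediate early gene Ier2 by 2.36 ± 0.16. Junb, a subunit of the transcription factor AP-1, rose by 2.15 ± 0.01. The others were Rprm at 2.54, Itm2c at 2.49, Ctla2a at 2.24, Nmb at 2.17 and Ctla2b at 2.15. Ly6a and Ly6c1, and Ctla2a and Ctla2b, are pairs of close relatives in sequence, and cross-reading between their probes was not tested. Among the largest falls, Ctss, a cathepsin of antigen-presenting cells, stood at -3.60 ± 0.08 and Ctsl, another cathepsin, at -2.26 ± 0.22. Anxa2 at -2.83, Spp1 (osteopontin) at -2.66, Bcl2a1b, a BCL2 family member, at -2.43, Mmp14 at -2.12 and Egfl7 at -2.06 were also in this group. Dtymk, the thymidylate kinase of DNA precursor synthesis, was at -2.11 ± 0.06 and the mitochondrial ribosomal protein gene Mrps28 at -2.06 ± 0.20. With the scanner software's ratios Bcl2a1b was at -3.98 and Mmp14 at -3.47.

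Of 12 tested mast cell protease and granule genes, 9 rose and 1 fell, the same counts when adjusted over the list alone. The list's median log2 ratio was 1.36, and camera gave an adjusted p = 1.27e-12, against an adjusted p = 0.727 with an estimated correlation. Cma1, a mast cell chymase, at 2.99 ± 0.59 and the tryptase Tpsab1 at 2.26 ± 0.80 were saturated at day 20 on both arrays, so these ratios do not give the size of their rises. With median centring they were 2.64 and 1.88. Mcpt1, another chymase of mucosal mast cells, rose by 1.58 ± 0.11 and was saturated at day 20 on 1 array. Mcpt1 and Mcpt2, and the tryptases Tpsab1 and Tpsb2, are likewise close paralogs. Tpsg1, a membrane tryptase, rose by 1.50 ± 0.01, Srgn, which encodes the core protein of granule proteoglycans, by 1.17 ± 0.18, and Gzmb, granzyme B, by 1.11 ± 0.20. Htra1, a secreted serine protease, rose by 2.18 ± 0.17. Htra1 and Havcr2 were named in advance. From general knowledge and not from the labels, this research group was understood to have reported them in such cells. The rise of Htra1 is therefore not independent evidence. It is nonetheless 1 of the 9 list genes that rose and enters the list's median and camera p, and no value without it is given here. Havcr2 was not analysed here. Mcpt4, a chymase of connective tissue mast cells, had a log2 ratio of 0.24 ± 0.03 and did not pass the test. Prg2, a granule protein that is also on the eosinophil list, fell, with a log2 ratio of -0.41 ± 0.05. It did not pass with a normexp offset of 0, the scanner software's ratios, median centring, or an intensity trend with a robust prior.

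Among 22 tested mast cell receptor and signalling genes, 13 rose and 0 fell, and 15 rose when adjusted over the list alone. The median was 0.64, with a camera adjusted p = 1.17e-11 and an adjusted p = 0.727 with an estimated correlation. Beside Fcer1a, Ms4a2, the beta chain of the same receptor, rose by 0.65 ± 0.12 with a probe that the files describe by the synonym Ms4a1. Fcer1g, the shared gamma chain, was at -0.03 ± 0.21 and did not pass. Il4ra, the IL-4 receptor alpha chain, rose by 1.99 ± 0.34, the IL-3 receptor gene Il3ra by 1.24 ± 0.41 and the kinase gene Btk by 1.13 ± 0.75. Itgae, the integrin alpha chain of CD103, which TGF-β induces in mucosal mast cells, rose by 1.25 ± 0.36. Itga2b, an integrin chain of platelets and young mast cells, rose by 1.74 ± 0.15. Il1rl1, the IL-33 receptor, had a log2 ratio of 0.30 ± 0.26 and an adjusted p of 0.135 with limma. Kit, the receptor for stem cell factor, had an outlier-marked spot on array 2 and was left out of the test, as was Cpa3, the mast cell carboxypeptidase. With marked spots kept, Kit was 3.03-fold higher at 1.60 ± 0.12, with an adjusted p of 1.25e-06. Cpa3 was at 2.05 ± 0.47 on the same terms, with day 20 saturated on both arrays and an adjusted p of 1.28e-06. Ms4a2 did not pass with the scanner software's ratios or with median centring in place of loess.

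Some genes for the making of mast cell mediators rose and others fell. Of 11 tested genes for histamine, serotonin and eicosanoid synthesis, 2 rose and 3 fell, the same counts when adjusted over the list alone, with a median of -0.10 and a camera adjusted p = 0.285 (0.856 with an estimated correlation). With the scanner software's ratios the median was -0.48, and over 13 other settings with the preset correlation the camera adjusted p lay between 0.0997 and 0.584. Hdc, the enzyme that makes histamine, was 2.43-fold lower at -1.28 ± 0.14. Ptgs1, cyclooxygenase 1, stood at -1.12 ± 0.35 and Ltc4s, leukotriene C4 synthase, at -0.97 ± 0.75. Tph1, the first enzyme of serotonin synthesis, rose by 0.85 ± 0.00, and Hpgds, which makes prostaglandin D2, by 0.54 ± 0.25. Among 28 cytokine and chemokine genes, 4 rose and 2 fell, or 4 and 3 when adjusted over the list alone, and the list's median was -0.03 with a camera adjusted p = 0.834 (0.954 with an estimated correlation). Ccl9 at 0.87 ± 0.05, Ccl2 at 0.75 ± 0.18 and Il16 at 0.64 ± 0.02 were higher, and Ccl17 at -1.30 ± 0.21 was lower. The scanner software's ratio of Ccl17 was -2.11. Tph1, at 0.51, did not pass with median centring, Ccl2 not with the scanner software's ratios, and Ltc4s with neither.

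Of 18 tested targets of STAT5 and cytokine signalling, 8 rose and 1 fell, or 9 and 2 when adjusted over the list alone, with a median of 0.28. The camera adjusted p = 0.00216, and the adjusted p = 0.761 with an estimated correlation. Socs3, a feedback inhibitor of cytokine receptors, rose by 1.83 ± 0.06, the kinase gene Pim1 by 0.90 ± 0.31, Stat5a by 0.89 ± 0.20 and Jak2 by 0.74 ± 0.16, while Myc, a driver of cell growth, stood at -0.64 ± 0.32. Among 22 TGF-β pathway genes, 5 rose and 4 fell, also when adjusted over the list alone, with a median of 0.05 and a camera adjusted p = 0.269 (0.843 with an estimated correlation). Besides Itgae, Bhlhe40 rose by 0.91 ± 0.15 and Id2 by 0.62 ± 0.25, while Tgfbi, an extracellular protein induced by TGF-β in many cells, stood at -1.82 ± 0.30. Of 27 transcription factors of blood cells, 7 rose and 5 fell, or 9 and 6 when adjusted over the list alone, with a median of 0.09 and a camera adjusted p = 0.285 (0.843 with an estimated correlation). Mitf, a factor that mast cells need, rose by 0.89 ± 0.24, Egr1 by 1.38 ± 0.30 and Gata1 by 0.51 ± 0.31. Klf1, the factor of red cell development, stood at -1.32 ± 0.11, Zfpm1, which encodes a partner of GATA-1, at -0.93 ± 0.11 and Klf4, a factor of monocytes, at -0.96 ± 0.01. Gata2 was not analysed here. Gata1 and Id2 did not pass with the scanner software's ratios or with median centring. By the scanner software Tgfbi was at -2.94, Klf1 at -2.19, Klf4 at -2.01 and Gata1 at 0.81.

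Markers of other cell types moved beside the mast cell genes. Of 20 tested neutrophil genes 0 rose and 10 fell, or 11 when adjusted over the list alone, with a median of -0.43, a camera adjusted p = 4.24e-11 and an adjusted p = 0.727 with an estimated correlation. S100a8, the partner of S100a9, stood at -3.06 ± 0.46, Ms4a3, a gene of granulocyte precursors, at -1.78 ± 0.26 and Elane, neutrophil elastase, at -0.88 ± 0.05. Of 30 monocyte and macrophage genes 5 rose and 17 fell, also when adjusted over the list alone, with a median of -0.43, a camera adjusted p = 3.75e-05 and an adjusted p = 0.727 with an estimated correlation. Lyz2, the lysozyme of myeloid cells, stood at -2.88 ± 0.53, Apoe at -2.19 ± 0.21 and the macrophage receptor gene Trem2 at -1.72 ± 0.03. The 5 members that rose were F13a1, Ly6c1, the chemokine receptor gene Ccr2 (0.99 ± 0.34), the endotoxin receptor gene Tlr4 (0.87 ± 0.14) and Marco (0.42 ± 0.27). Of 15 dendritic cell and MHC class II genes 1 rose and 6 fell, also when adjusted over the list alone, with a median of -0.21, a camera adjusted p = 0.0185 and an adjusted p = 0.727 with an estimated correlation. Ccr7 at -0.94 ± 0.25, Cd83 at -0.89 ± 0.15 and H2-DMb1 at -0.69 ± 0.03 were lower, and Cst3, which encodes the protease inhibitor cystatin C, was higher at 0.97 ± 0.17. With the scanner software's ratios the neutrophil and dendritic cell medians were -1.01 and -0.36, S100a8 was at -4.96, Cd83 at -2.36, H2-DMb1 at -2.02 and Ccr7 at -1.83, and with a normexp offset of 0 the monocyte median was -0.86.

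Mcpt8, a protease of basophils, fell, with a log2 ratio of -2.78 ± 0.10. It belonged to 7 tested eosinophil and basophil genes, of which 0 rose and 3 fell, or 4 when adjusted over the list alone, with a median of -0.30, a camera adjusted p = 0.0108 and an adjusted p = 0.727 with an estimated correlation. With outlier-marked spots kept, which brought in Cpa3 and Cd200r3, the median was -0.09 and the camera adjusted p = 0.584. Epx, eosinophil peroxidase, stood at -0.45 ± 0.18. Of 18 erythroid genes 0 rose and 9 fell, also when adjusted over the list alone, with a median of -0.32, a camera adjusted p = 1.37e-06 and an adjusted p = 0.727 with an estimated correlation. Hemgn, a nuclear protein of blood-forming cells, stood at -1.99 ± 0.08, carbonic anhydrase 1 (Car1) at -1.20 ± 0.14 and alpha globin (Hba-a1) at -1.05 ± 0.25. Hemgn and Car1 were not well above background at day 20 on 1 array, and by the scanner software their ratios were -4.78 and -4.27, the median of the erythroid list -0.56 and that of the eosinophil and basophil list -0.48. Of 18 B lineage genes 1 rose and 3 fell, or 1 and 5 when adjusted over the list alone, with a median of -0.13, a camera adjusted p = 0.0394 and an adjusted p = 0.727 with an estimated correlation. Cd24a, which many young blood cells carry, stood at -1.43 ± 0.02, Cd79b at -0.50 ± 0.11 and Jchain at -0.35 ± 0.04. Outside the list, accession-only probes described as the immunoglobulin mu constant region stood at -2.72 ± 0.30 and -1.66 ± 0.02. Epx, Cd79b and Jchain did not pass with median centring, and other settings gave ratios as low as -1.09, -1.10 and -1.18 for them and -0.23 for the B lineage median. The B lineage camera adjusted p was 0.0622 when all 4 channels had to be well above background.

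The remaining cell type lists did not pass with camera. By fry's test for change in either direction the stromal and progenitor lists passed, each with an adjusted p = 0.0339. Of 20 T and NK cell genes 0 rose and 1 fell, Gzma (granzyme A) at -0.62 ± 0.51, also when adjusted over the list alone, with a median of -0.06 and a camera adjusted p = 0.269 (0.843 with an estimated correlation). Outside the list, accession-only probes described as T cell receptor gamma constant regions stood at -1.915 ± 0.04 and -1.455 ± 0.01. Of 12 megakaryocyte genes 3 rose and 4 fell, also when adjusted over the list alone, with Gp1ba at 1.53 ± 0.19, Cd9 at -0.95 ± 0.06 and Clec1b at -0.56 ± 0.21. Their median was -0.02 while their mean was 0.10 and the camera direction was up, with an adjusted p = 0.943 (0.985 with an estimated correlation). Of 15 stromal genes 2 rose, Tagln at 0.64 ± 0.68 and Acta2 at 0.55 ± 0.25, and 0 fell, also when adjusted over the list alone. The stromal median was -0.03, the mean was above 0 at 0.0013 and the camera direction was down, with an adjusted p = 0.877 (0.985 with an estimated correlation). Of 17 progenitor genes 4 rose and 1 fell, or 5 and 1 when adjusted over the list alone, with a median of 0.01 and a camera adjusted p = 0.269 (0.727 with an estimated correlation). Beside Ly6a, Tek rose by 0.61 ± 0.03, with day 4 not well above background on 1 array, and Cd93 by 0.49 ± 0.32. With outlier-marked spots kept, which brought in Kit and Cd34, the progenitor list had a median of 0.02 and passed at a camera adjusted p = 0.0456. Tagln, Acta2 and Cd93 did not pass with the scanner software's ratios or with median centring, nor Gzma and Clec1b with median centring. By the scanner software Gzma was at -1.50, Clec1b at -1.78 and Tek at 1.89, and with median centring Acta2 was at 0.36.

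**Figure D2:**
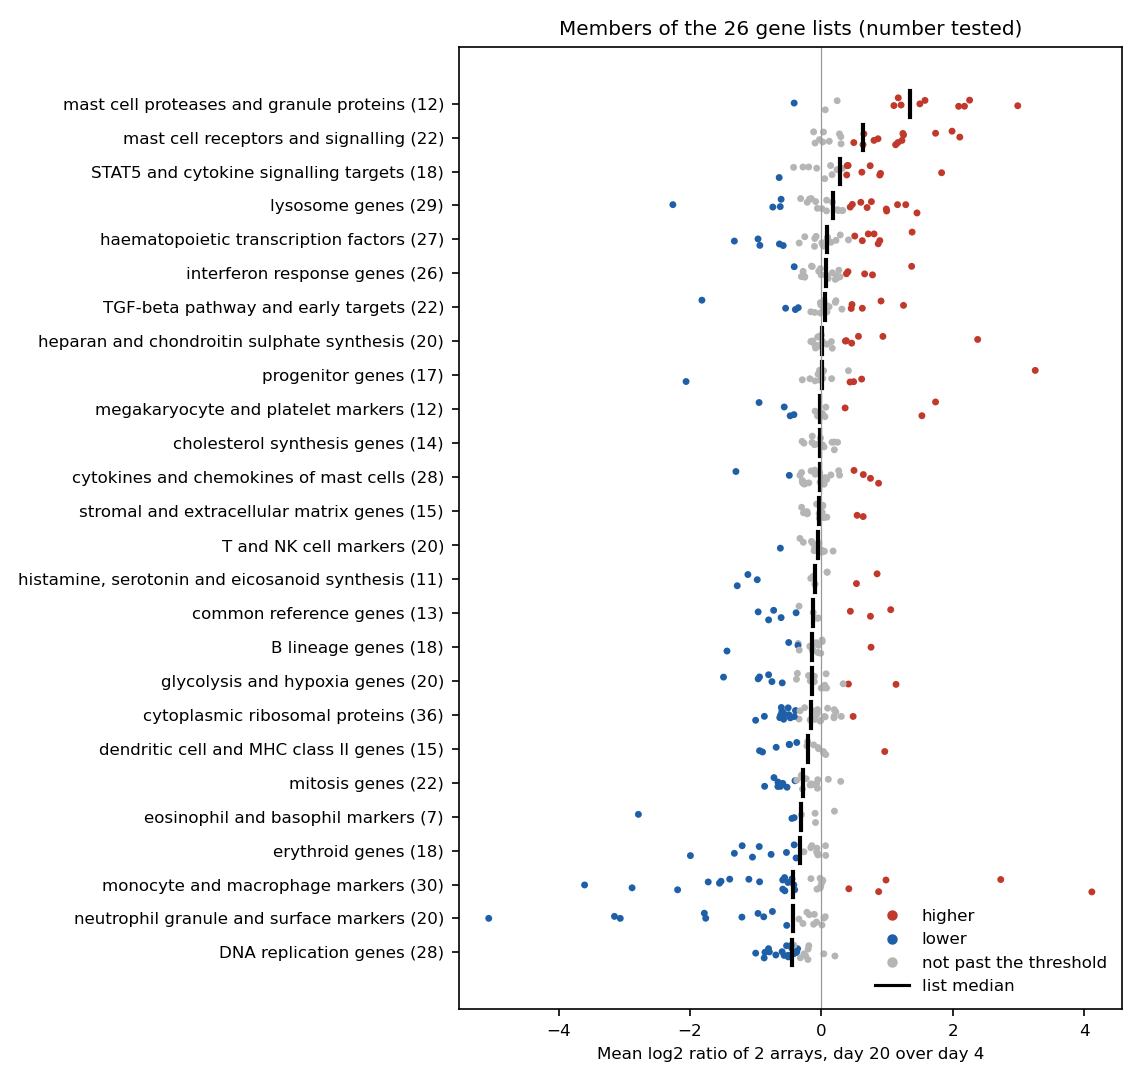
Mean log2 ratio of 2 arrays, day 20 over day 4 (horizontal axis), of every tested member of 26 gene lists, coloured by the test, with a black bar at each list's median and the number tested in brackets. Medians run from 1.36 for the mast cell protease list to -0.44 for the DNA replication list.

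Of 28 DNA replication genes 0 rose and 19 fell, or 20 when adjusted over the list alone, with a median of -0.44, a camera adjusted p = 5.85e-11 and an adjusted p = 0.727 with an estimated correlation. Orc1 and Orc6 of the origin recognition complex stood at -0.998 ± 0.24 and -0.87 ± 0.27, cyclin E1 (Ccne1) at -0.86 ± 0.17 and the helicase gene Mcm2 at -0.80 ± 0.18. Of 22 mitosis genes 0 rose and 8 fell, or 9 when adjusted over the list alone, with a median of -0.28, a camera adjusted p = 6.99e-05 and an adjusted p = 0.727 with an estimated correlation. The mitosis median was -0.45 on array 1 and -0.10 on array 2, and 14 of 22 members had the same direction on both arrays. The centromere histone gene Cenpa stood at -0.86 ± 0.14, the kinase gene Plk1 at -0.72 ± 0.16, Cdc25c at -0.66 ± 0.03 and cyclin B1 (Ccnb1) at -0.66 ± 0.15. Of 36 cytoplasmic ribosomal protein genes 1 rose and 14 fell, or 2 and 16 when adjusted over the list alone, with a median of -0.16, a camera adjusted p = 0.000528 and an adjusted p = 0.727 with an estimated correlation. Rpl14 stood at -0.999 ± 0.003, Rps2 at -0.87 ± 0.26, Rps19 at -0.63 ± 0.23 and Rpl12 at -0.62 ± 0.41. Mcm2, Plk1, Cdc25c, Ccnb1, Rps2, Rps19 and Rpl12 did not pass with the scanner software's ratios. With median centring the ribosomal protein list had a median of -0.46 and Rpl12 was at -0.95.

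Of 20 glycolysis and hypoxia genes 2 rose and 6 fell, or 3 and 8 when adjusted over the list alone, with a median of -0.14, a camera adjusted p = 0.0288 and an adjusted p = 0.727 with an estimated correlation. Their median was -0.37 on array 1 and -0.03 on array 2, and 15 of 20 had the same direction on both arrays. Egln3, an oxygen-sensing hydroxylase, stood at -1.49 ± 0.25 with day 20 not well above background on 1 array, the glycolytic gene Pgk1 at -0.96 ± 0.01 and the lactate carrier gene Slc16a3 at -0.94 ± 0.08. Ndr1, the older symbol in the files for N-myc downstream regulated gene 1, rose by 1.14 ± 0.14. Of 29 lysosome genes 10 rose and 4 fell, or 12 and 5 when adjusted over the list alone, with a median of 0.17, a camera adjusted p = 0.0260 and an adjusted p = 0.843 with an estimated correlation. Their median was 0.004 on array 1 and 0.27 on array 2, and 22 of 29 had the same direction on both arrays. Man2b1, lysosomal alpha-mannosidase, rose by 1.46 ± 0.06, Laptm5 by 1.29 ± 0.07 and Cd63, a membrane protein of mast cell granules, by 1.16 ± 0.50. Of 20 genes for heparan and chondroitin sulphate, the sugar chains of granule proteoglycans, 6 rose and 0 fell, also when adjusted over the list alone, with a median of 0.01, a camera adjusted p = 0.0394 and an adjusted p = 0.761 with an estimated correlation. Besides Hs3st1, Ndst2, the sulphotransferase of mast cell heparin, rose by 0.94 ± 0.38, Hs6st2 by 0.57 ± 0.13 and Hs2st1 by 0.46 ± 0.30. With the scanner software's ratios the glycolysis, lysosome and heparan lists had a camera adjusted p = 0.0962, 0.0997 and 0.229. Cd63, Ndst2, Hs6st2 and Hs2st1 did not pass with median centring. By the scanner software Egln3 was at -3.48 and Hs6st2 at 1.28.

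Of 26 interferon response genes 5 rose and 1 fell, also when adjusted over the list alone, with a median of 0.08 and a camera adjusted p = 0.206 (0.852 with an estimated correlation). Tap2, a peptide transporter of antigen presentation, rose by 1.38 ± 0.69, Stat2 by 0.78 ± 0.18 and Irf1 by 0.66 ± 0.15, while Isg20 stood at -0.41 ± 0.16. Of 14 cholesterol synthesis genes 0 passed in either direction with limma, also when adjusted over the list alone, and 2 (Dhcr7 at -0.26 and Pmvk at -0.29) had an unadjusted p below 0.05, with a median of -0.02 and a camera adjusted p = 0.943 (0.985 with an estimated correlation). Of 13 common reference genes 3 rose and 5 fell, or 3 and 6 when adjusted over the list alone, with a median of -0.12 and a camera adjusted p = 0.178 (0.727 with an estimated correlation). Ywhaz rose by 0.75 ± 0.20 and B2m by 0.44 ± 0.16, while Gapdh stood at -0.80 ± 0.18, Hprt at -0.72 ± 0.24 and Gusb at -0.61 ± 0.41. The reference list passed with median centring, at a median of -0.29 and a camera adjusted p = 0.0237. By fry's test for change in either direction the reference list also passed, with an adjusted p = 0.0339. Isg20, Irf1 and Ywhaz did not pass with the scanner software's ratios or with median centring, nor Gapdh with the former and Tap2 with the latter, and by the scanner software Isg20 was at -0.78 and Stat2 at 1.19.

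**Figure D3:**
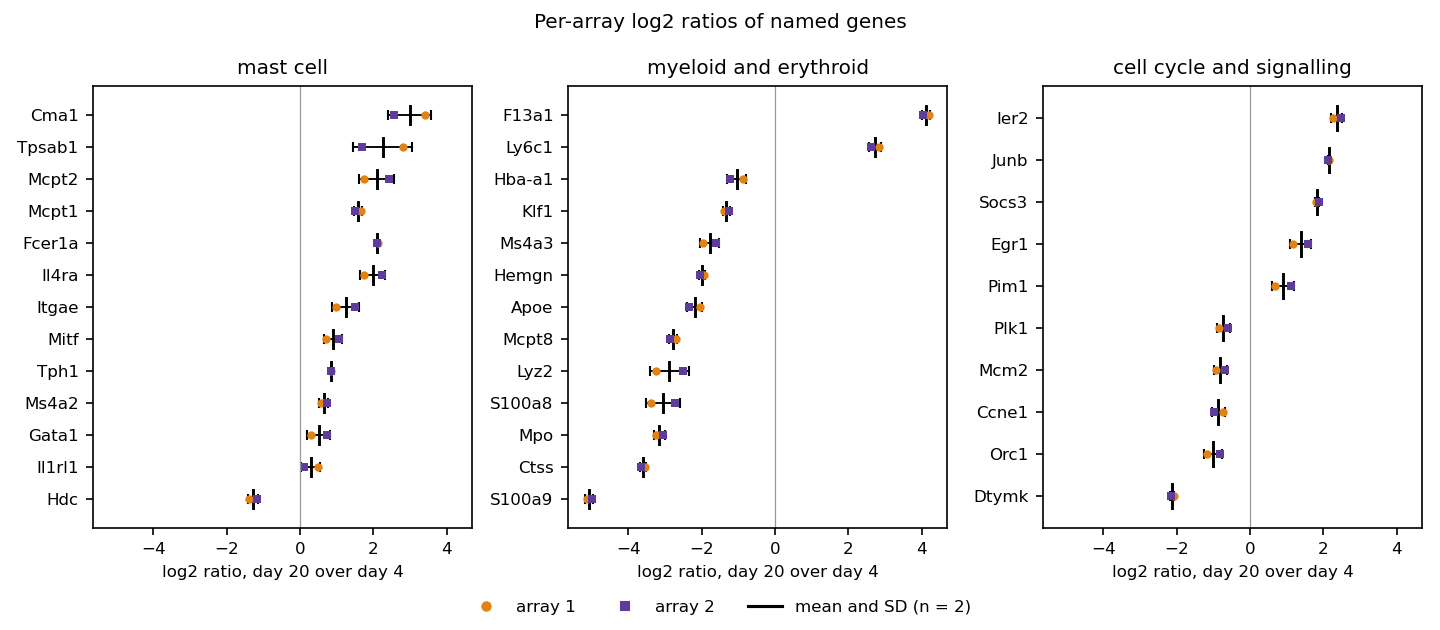
Log2 ratio of day 20 over day 4 on array 1 (circles) and array 2 (squares) for named genes of 3 groups, with the mean and SD as bars (n = 2). S100a9 lies furthest to the left at -5.06 and F13a1 furthest to the right at 4.12, Il1rl1 is the gene shown that did not pass the test, and the ratios of Cma1 and Tpsab1 are limited by saturation at day 20.

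Across the 26 lists camera with a preset correlation of 0.01 placed 15 past the threshold, 5 higher and 10 lower. With an estimated correlation 0 passed, where the smallest camera adjusted p was 0.727 and 0 had an unadjusted p below 0.05. With 1 residual degree of freedom a list could hardly pass that test, so it does not decide whether the lists moved. The p-values with the preset correlation measure spread across genes and not between the 2 arrays. They do not show whether a shift would repeat in other cultures. With fry, 0 lists passed as moving on balance in a single direction (smallest adjusted p 0.0919, 6 with an unadjusted p below 0.05) and 9 passed as changing in either direction. Of the genes past the limma threshold, 1 had arrays pointing opposite ways, C1ql1, at -1.76 on array 1 and 0.06 on array 2, which is named because of this after its values were seen. The median absolute log2 ratio of the genes that passed was 0.60. The counts rest on 2 arrays with 1 residual degree of freedom per gene, and with the scanner software's own log ratios 612 genes were higher and 627 lower, with median centring 559 and 784.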

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

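The tests with background means in place of medians and with a maximum-likelihood prior were chosen after the results were seen, and the others were planned. Of 109 named genes past the threshold, 77 passed under each other setting that tested them (13, or 12 for Hemgn, Car1, Tek and Egln3), 32 were lost under at least 1, and 22 of these only with the scanner software's ratio or median centring, while 0 of 110 tested named genes took the opposite sign. The Results do not name every setting in which a gene was lost. For example, Tagln passed in 6 of 13 other settings and Jchain in 8 of 13. The log2 ratios of 26 named genes moved by over 1.5 times under at least 1 setting, 24 of them to larger changes. Of 15 called lists, 10 passed in 13 of 13 settings, which leave out the other list tests below, where 0 passed. Exceptions were the heparan list (7 of 13), the lysosome and glycolysis lists (9 each), and the B lineage and eosinophil lists (12 each). Not all of these settings are separate checks of a list. The series matrix repeats the scanner software's ratio, and the changed variance priors cannot alter a list's result.

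With the scanner software's log ratio, and equally the series matrix, 612 genes were higher, 627 lower, 317 at least 2-fold higher and 364 at least 2-fold lower on both arrays. These settings kept 1169 of the 3092 calls in direction, and 0 turned. Median centring gave 559 higher and 784 lower and kept 1339 calls. A normexp offset of 0 gave 309 at least 2-fold higher and 331 lower, where the offset of 50 draws dim ratios towards 0 by its construction. The cause was not tested for the other changes. Leaving out an array gave 244 to 339 genes at least 2-fold higher and 195 to 373 lower, because a gene then has to pass on 1 array. Camera with an estimated correlation and fry each called 0 lists, with 0 and 6 at an unadjusted p below 0.05, against 15 with the preset correlation and 9 with fry's test for either direction. The former could hardly call any list with so few arrays. With the maximum-likelihood prior 1113 genes were higher and 1333 lower (2446 calls kept), and with background means 1199 and 1431. The median log2 ratio of all genes lay between -0.0184 and -0.00391 over these settings. Signal over background limits what dim genes can show: the share of gene spots well above background was lowest, 80.0%, for day 4 on array 2, and net signal over negative controls was lowest, 1.65, for day 20 on array 2.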

Other observations

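The gene families in this part and its tests of them and of explanations were chosen after the results were seen, while the cell type and STAT5 lists were fixed earlier. Families of growth and energy supply were placed lower by camera with a preset correlation. Of 58 respiratory chain genes 2 were higher and 43 lower at day 20, with a median log2 ratio of -0.59, a camera adjusted p = 7.63e-23 over 19 families, and an adjusted p = 0.640 with an estimated correlation. Of 45 mitochondrial ribosomal protein genes 0 were higher and 29 lower (median -0.48), and of 17 mitochondrial import genes 0 and 14 (median -0.74), with adjusted p = 1.87e-18 and 6.78e-14, and 0.640 for both with an estimated correlation. The higher respiratory chain genes were Cox7a2l at 0.75 ± 0.11 and Sdhaf2 at 0.52 ± 0.40. Cycs, cytochrome c, stood at -1.35 ± 0.03 and Timm8a1, an import gene, at -1.71 ± 0.03 (SD, n = 2). Of 25 ribosome assembly genes 0 were higher and 18 lower (median -0.63, adjusted p = 2.71e-14, or 0.640 with an estimated correlation), among them Rrp15 at -1.65 ± 0.23. Nucleotide synthesis, translation initiation, proteasome, cytosolic chaperonin, transfer RNA synthetase and heat shock families passed as lower too, and 0 of the 12 families that passed did so with an estimated correlation, where 0 had an unadjusted p below 0.05. As with the lists, a family could hardly pass that test with so few arrays. The small p-values with the preset correlation likewise measure spread across genes and not between the arrays.

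Families of MHC class I and immediate early genes were placed higher by camera with a preset correlation. Of 15 MHC class I genes 11 were higher and 0 lower, with a median of 0.81, an adjusted p = 5.09e-09 and an adjusted p = 0.640 with an estimated correlation. H2-T23 rose by 1.34 ± 0.47 and H2-Q7 by 1.32 ± 0.40, and these genes are close paralogs whose cross-reading was not tested. Of 34 immediate early genes 15 were higher and 2 lower (median 0.32, adjusted p = 1.67e-06, or 0.640 with an estimated correlation). Gadd45g rose by 1.79 ± 0.21, Jun by 0.88 ± 0.05 and Fos by 0.35 ± 0.09, while the kinase gene Sgk1 stood at -1.32 ± 0.23 and Dusp1 at -0.46 ± 0.16. Families for endoplasmic reticulum stress, cathepsins and cystatins, integrins, annexins and S100 proteins, Rab GTPases, the vacuolar proton pump and histones did not pass. Among 284 genes tested only with outlier-marked spots kept, 58 were higher and 42 lower: Pf4, a platelet and mast cell chemokine, stood at -3.56 ± 0.24, and Itgb7, the integrin chain that pairs with the product of Itgae, rose by 1.41 ± 0.30. Of the probes known by an accession alone, that for calcitonin rose by 2.93 ± 0.10 and that for hsp60 stood at -1.87 ± 0.17.

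Camera placed the mast cell protease and receptor lists higher and the neutrophil and monocyte lists lower, each with an adjusted p = 0.727 with an estimated correlation, while F13a1 and Ly6c1 of the monocyte list rose (4.12 and 2.73) and the mediator genes Hdc, Ptgs1 and Ltc4s fell. A gene-specific dye bias would turn its sign between the swapped arrays and cancel in their mean, on which the lists were called. The swap itself therefore argues against it as the main cause of the pattern. The log2 ratios of 83 members of the 4 lists had an r of 0.970 across genes. Lists called in opposite directions on that mean favour a high r, so it is no separate test. Smaller dye effects in single genes are not excluded. A larger share of mast cells with an unchanged profile of each cell would raise mast cell genes alike only if other cells lacked them. Across 4 bright, unsaturated ones, from Fcer1a at 2.11 to Ms4a2 at 0.65, the SD was 0.784 against a pooled replicate SD of 0.249. But basophils express both of these genes and their protease gene Mcpt8 stood at -2.78, so these unequal rises do not exclude a larger share. The others, Mcpt2 at 2.09 ± 0.48 and Tph1 at 0.85 ± 0.004, were listed as not shared with basophils and also rose unequally. That goes against a larger share alone if other cells lacked both genes, but they are too few to decide. A larger share may still give the pattern, alone or beside maturing mast cells. These cannot be told apart, since the pools were not sorted by any step that the labels name.

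Of 34 immediate early genes 15 were higher, 2 lower and 17 did not pass, with an adjusted p = 0.640 for the family with an estimated correlation. Their log2 ratios on both arrays had an r of 0.925 across 34 genes. The family was chosen after the results were seen, so this r is no separate test of dye bias. Such a bias would cancel in the mean of the swapped arrays, while smaller effects in single genes are not excluded. A heat shock type of stress at the day 20 harvest may raise the immediate early genes. Of 16 heat shock genes 0 were higher and 6 lower, with a median of -0.14. Camera placed the family lower with an adjusted p = 0.00258 (0.646 with an estimated correlation). These values go against that explanation, but the family held only genes with a plain symbol. Accession-only probes were outside it: that for hsp68 rose by 3.27 ± 0.26 and that for hsp60 stood at -1.87 ± 0.17. These data therefore leave the explanation open. Stronger cytokine signalling in the later culture stays open: 8 of 18 STAT5 and cytokine targets rose and 1 fell, with a camera adjusted p = 0.00216 and an adjusted p = 0.761 with an estimated correlation.

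Of 145 mitochondrial and ribosome assembly genes 2 were higher and 104 lower, with a median of -0.60 and an adjusted p = 0.640 with an estimated correlation for each of their 4 families. Loess, which moved single genes by up to 0.43, took their median from -0.68 to -0.60, still below 0 by more than the SD of 0.42 across members, which argues against the trend along intensity that it removed as the whole cause. A gene-specific dye bias would turn its sign and cancel in the mean of both arrays. The higher of both arrays' medians was -0.53, but the families were chosen after the results were seen, so this is no separate test. Arguing against these technical causes does not show a biological cause. The lower values may reflect a biological change that goes with slower growth, a hypothesis found on these same data. Neither it nor other technical causes were tested. Loss of fast-growing immature cells was not tested and could give the same values.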
